A study of Caenorhabditis elegans with 12 samples.

How the data were processed

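RNA of whole L4 worms, extracted with Trizol, was sequenced by the submitters as stranded paired-end libraries of 100-base reads, with 3 biological replicates of wildtype, mrps-38(P210L), lonp-1(cmh24) and the double mutant. Per the submitters' processing notes, reads were aligned to WBcel235 with STAR, counted per gene with featureCounts and normalized with DESeq2 (versions and the annotation release were not given in the sources used here). The authors deposited 2 tables of 19568 genes (17798 protein-coding genes, 1079 pseudogenes and 691 others), 1 with a DESeq2 normalized count per gene and library (a signal scaled by 1 size factor per library) and 1 with FPKM. Gene names, types and 1-based positions were those given in the deposited tables. Reference annotations, among them Ensembl release 115 of WBcel235, were used to match entries of the gene lists to these genes. All 12 columns of each table were matched to a library.

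In the authors' normalized counts each value was a whole multiple of 1 step per library (100.0% of values within 0.01), so the whole reads were recovered. They summed to 22614493 to 22890539 reads in genes per library, with size factors of 0.8479 to 1.2153. FPKM recomputed from these reads differed from the authors' FPKM by a relative deviation of at most 1.9e-14, so the FPKM table is the same reads scaled to the total per library. The smallest read total of a gene over the 12 libraries was 10. Counting error is small at this depth, and floors of 3 reads per library, used where a group had none, cover counting error only.

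The main test was limma (3.58.1, in R 4.3.3, with statmod 1.5.0) with an intensity trend and robust empirical Bayes, on log2 of the authors' normalized count + 1. All 12 libraries entered 1 fit with a mean per group, and genes with a mean normalized count of at least 10 (15717) were tested, two-sided, with Benjamini-Hochberg adjustment at 0.05. There were 6 contrasts, lonp-1(cmh24) and mrps-38(P210L) against wildtype, the double mutant against each of the other 3 groups, and the interaction. Gene lists, 51 with 1059 entries or name patterns (88 entries had no match in the table), were tested with camera at a preset inter-gene correlation of 0.01 where they had at least 5 tested members (50 lists), and again with an estimated correlation and with fry, which tests whether the genes of a list move on balance 1 way. Genes changed back are those called in lonp-1(cmh24) against wildtype and called in the opposite direction in the double mutant against lonp-1(cmh24). The share of the change reversed was cross-fitted, so that genes at least 2-fold changed were picked with 1 replicate of both groups left out and measured in the libraries left out. The slope between the effects of the lonp-1 mutation in both backgrounds is across genes.

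The groups, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule takes, per comparison, the 8 largest changes in each direction (6 for the interaction and for genes changed back) among called genes with a mean of at least 50 and no overlap between the groups, always lonp-1, mrps-38, hsp-6, hsp-60, atfs-1 and the 12 mitochondrial mRNAs, and from each called list, or list with at least 3 called members, up to 4 passing members with the largest change and 2 with the highest mean. The condition of no overlap was applied to comparisons of 2 groups and not to the interaction. The text draws on the genes so named. mrps-38 and atf-4 were not analysed here.

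Alternatives covered the pseudocount (0.5 and 5), the filter (none, and a mean of at least 50), TMM factors, median-ratio factors from genes outside the maturation lists, the FPKM table (log2 of FPKM + 0.1, mean FPKM of at least 0.5), edgeR's quasi-likelihood test (4.0.16) and DESeq2 (1.42.0) on the recovered reads, a replicate block, fits of only the groups compared, arrayWeights, empirical Bayes without the robust option, and each library left out in turn. Scaling of the recovered reads to total reads, and TMM factors for the list tests, were added after the data were seen. On simulated data with the depth and spread of these libraries, limma recovered 56%, 78%, 94% and 98% of genes changed 1.5-, 2-, 4- and 8-fold, with 9 false calls among 15517 unchanged genes. Unlike in the real comparisons, few genes were changed, as many up as down, and the size factors were known. The simulation therefore says nothing about errors that come from the scaling. For each comparison the libraries were also divided in other ways (10 splits of 6 libraries, 100 random splits of the interaction and of genes changed back) and the counts taken again.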

Results

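Total RNA of whole Caenorhabditis elegans worms at the L4 larval stage, fed HT115 E. coli, was sequenced in 12 libraries, 3 biological replicates of each of 4 genotypes. The genotypes were wildtype, mrps-38(P210L), lonp-1(cmh24) and the double mutant that carried both mutations. lonp-1 encodes the LON protease of the mitochondrial matrix, and mrps-38 encodes a protein of the small subunit of the mitochondrial ribosome. Each library held 22614493 to 22890539 reads in the 19568 genes of the table, of which 18072 to 19209 were detected per library. Of these genes, 15717 had a mean normalized count of at least 10 and were tested. Gene values below are log2 fold changes ± SE from limma with n = 3 libraries per group, and a gene or list is said to rise or fall where its Benjamini-Hochberg adjusted p was under 0.05. Genes of multi-copy families (msp, col, vit and his) share sequence, so the assignment of reads to single members is uncertain.

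The lonp-1 transcript itself (WBGene00016391, WBcel235, chromosome I, 10676922 to 10682374) was present in all 4 genotypes. Its normalized count was 1688 ± 62 in wildtype, 1613 ± 49 in mrps-38(P210L), 1339 ± 5.8 in lonp-1(cmh24) and 1437 ± 44 in the double mutant (SD, n = 3). It was lower in lonp-1(cmh24) than in wildtype by a log2 fold change of -0.33 ± 0.05 (adjusted p = 3.4e-05). Under scaling to total reads that change was -0.1 and did not pass (adjusted p = 0.113 on FPKM and 0.0991 on the recovered reads, within a range of 3.2e-09 to 0.113 over all alternatives). The transcript of mrps-38 was not analysed here.

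The 4 genotypes differed in transcripts that mark sexual maturation. Yolk proteins (vitellogenins), made by the adult intestine, took 0.0017 ± 0.0018% of reads in mrps-38(P210L), 0.104 ± 0.0086% in wildtype, 0.949 ± 0.17% in lonp-1(cmh24) and 2.45 ± 0.0087% in the double mutant (SD, n = 3). Major sperm proteins, which are made in sperm precursors, took 0.0072 ± 0.0082%, 0.117 ± 0.0058%, 0.161 ± 0.007% and 0.744 ± 0.017% in the same order. The first principal component held 74.3% of the variance and placed the groups in that order too, from -173.8 for an mrps-38(P210L) library to 118.8 for a double mutant library. Replicate 3 of mrps-38(P210L) stood apart from the other libraries of its group, with 0.0038% of reads in vitellogenins against 6e-04% and 7e-04%, and 0.0167% in major sperm proteins against 0.0025% and 0.0024%. These measured differences in maturation markers accompany every comparison described here.

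**Figure D1:**
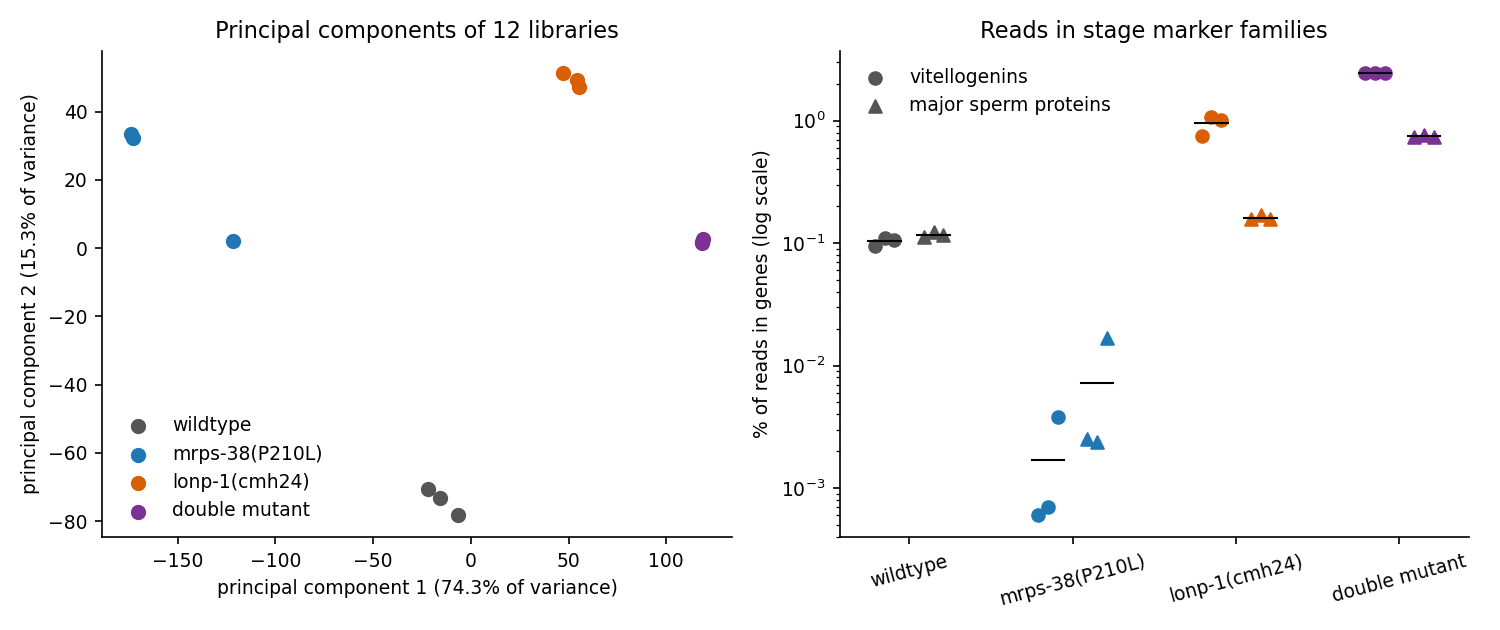
Left, the 12 libraries on the first 2 principal components of log2 normalized counts (74.3% and 15.3% of the variance), coloured by genotype. Right, the percent of reads in vitellogenins and in major sperm proteins on a log axis, with points for libraries and lines for group means (n = 3), where the means run from 0.0017% to 2.45% and from 0.0072% to 0.744% between mrps-38(P210L) and the double mutant.

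The comparison of lonp-1(cmh24) with wildtype asked how the mutation of the mitochondrial protease alone changed transcript levels. All 12 mRNAs encoded by mitochondrial DNA rose, with a median log2 fold change of 1.76 (camera adjusted p = 1.03e-06, and adjusted p = 0.237 with an estimated correlation). The largest rises were those of atp-6, a subunit of the ATP synthase (2.23 ± 0.11), nduo-2 (2.14 ± 0.32), nduo-5 (2.04 ± 0.09) and nduo-4 (1.92 ± 0.08), subunits of complex I, and ctc-1, a subunit of cytochrome c oxidase (1.87 ± 0.09). Both mitochondrial rRNA genes rose far more. The small-subunit rRNA gene MTCE.7 (MtDNA, 898 to 1593) went from 236 ± 32 to 6460 ± 1100 normalized counts, and the large-subunit gene MTCE.33 (MtDNA, 10403 to 11354) from 101 ± 21 to 3520 ± 620 (SD, n = 3). These are log2 fold changes of 4.76 ± 0.12 and 5.11 ± 0.15, or 27.2-fold and 34.4-fold (the 2 rRNA genes were chosen for naming after their values were seen). Mitochondrial genes took 0.67 ± 0.053% of reads in wildtype and 2.73 ± 0.38% in lonp-1(cmh24) (SD, n = 3).

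Nuclear genes of the mitochondrial stress response rose with them, 20 of 27 tested members higher and 4 lower (median 0.52, camera adjusted p = 5.98e-05, and adjusted p = 0.237 with an estimated correlation). Among them were hsp-6, the mitochondrial HSP70 (0.71 ± 0.08), atfs-1, the transcription factor of that response (0.64 ± 0.04), the flavin monooxygenase fmo-2 (3.95 ± 0.21), the cytochrome P450 gene cyp-14A4 (4.42 ± 0.13) and the heme transport gene hrg-9 (1.99 ± 0.08). The mitochondrial chaperonin hsp-60 fell (-0.42 ± 0.07). Factors of mitochondrial translation and tRNA charging were higher for 13 of 21 members and lower for 4, among them mttu-1 (1.35 ± 0.15) and the elongation factor tsfm-1 (0.86 ± 0.05), with a camera adjusted p = 0.0377, and adjusted p = 0.282 with an estimated correlation. Genes of mitophagy, fission and fusion rose in 20 of 26 cases and fell in 2, including allo-1 (1.65 ± 0.05), the fission GTPase drp-1 (1.08 ± 0.04) and the mitophagy receptor dct-1 (1.08 ± 0.09), with a camera adjusted p = 5.98e-05, and adjusted p = 0.0635 with an estimated correlation. polg-1, the mitochondrial DNA polymerase, rose by 1.1 ± 0.10.

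Lists of nuclear genes for respiratory complexes I, III and V, the TCA cycle and protein synthesis were lower. Complexes II and IV were not called (camera adjusted p = 0.343 and 0.108), and their medians of -0.14 and -0.10 became 0.09 and 0.12 on FPKM. Complex I subunits fell in 31 of 33 cases and rose in 1 (median -0.31), with nduf-9 at -0.50 ± 0.05. Complex III fell in 9 of 11 (median -0.38, ucr-1 at -0.50 ± 0.06) and complex V in 14 of 16 with 1 higher (median -0.36, asg-1 at -0.72 ± 0.05). The TCA cycle fell in 21 of 26 with 1 higher (median -0.27), with sucl-2 at -0.78 ± 0.07 and sucg-1 at -0.74 ± 0.05. Camera called all 4 lists (adjusted p = 4.68e-07 to 0.00499), and with an estimated correlation their adjusted p was 0.237 to 0.383. On FPKM fewer members passed, 15 lower and 2 higher for complex I (median -0.08), 6 and 1 for complex III (-0.15), 8 and 1 for complex V (-0.13), and 10 and 4 for the TCA cycle (-0.04). Proteins of the small mitoribosomal subunit fell in 18 of 28 cases and rose in 2 (median -0.32), but on FPKM they fell in 11 and rose in 9 (median -0.09). Those of the large subunit fell in 24 of 42 and rose in 2, where the median of -0.21 became 0.02 under FPKM scaling, with 9 lower and 8 higher (camera adjusted p = 0.0034 and 0.00085, and adjusted p = 0.287 for both with an estimated correlation). Cytosolic ribosomal proteins fell in 82 of 84 cases and none rose, with a median of -0.61 and rpl-34 at -0.85 ± 0.08 and rpl-3 at -0.66 ± 0.06 (camera adjusted p = 1.69e-17, and adjusted p = 0.286 with an estimated correlation). Proteasome subunits fell in 32 of 33, with pbs-5 at -0.63 ± 0.06 (median -0.37, camera adjusted p = 3.45e-09, and adjusted p = 0.166 with an estimated correlation), and on FPKM in 18 with 1 higher (median -0.14).

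In metabolism, 21 of 27 genes of the propionate shunt and methionine cycle fell and none rose, among them pmt-2, a methyltransferase of phosphatidylcholine synthesis (-1.49 ± 0.06), the hydrolase of S-adenosylhomocysteine ahcy-1 (-1.07 ± 0.12) and the serine hydroxymethyltransferase mel-32 (-1.14 ± 0.05). The fatty acid desaturase fat-7 fell by 4.57 on the log2 scale (SE 0.18). The acyl-CoA synthetase acs-2 rose by 3.35 ± 0.14 against the direction of its list, in which 24 of 43 genes of beta-oxidation fell and 9 rose (15 and 12 on FPKM, median -0.05). Glycolysis genes rose in 11 of 19 cases and fell in 3, with hxk-1, a hexokinase, at 1.61 ± 0.05 and gpd-1 at 1.53 ± 0.14. These 3 lists had medians of -0.63, -0.28 and 0.24 and camera adjusted p of 1.77e-06, 0.00563 and 0.0377, and with an estimated correlation their adjusted p was 0.237 to 0.47. The intracellular pathogen response rose in 21 of 29 cases and fell in 1 (median 1.18), led by pals-14 (5.05 ± 0.41) and pals-6 (4.65 ± 0.24). Cytochrome P450 genes rose in 36 of 61 and fell in 14 (median 0.68), led by cyp-13A8 (5.90 ± 0.27). Camera called both (adjusted p = 2.84e-05 and 0.000815), and with an estimated correlation their adjusted p was 0.273 and 0.237.

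Transcripts of the germline and of late-larval tissues separated these genotypes as well. All 37 oocyte and eggshell genes rose (median 2.62), among them meg-1 (5.81 ± 0.48) and nos-2 (5.63 ± 0.49), maternal mRNAs of the germline, and the eggshell gene perm-4 (3.17 ± 0.85). Vitellogenins rose in 5 of 6 cases (median 2.89, vit-5 at 3.73 ± 0.91), beside the higher share of reads given above. The count and the SE include the spread of replicate 3 of mrps-38(P210L). All 6 rose in a fit of only these 2 groups and without that library. Major sperm proteins rose in 0 of 31 cases and fell in 1 (median 0.33, camera adjusted p = 0.705). Those counts rest on a variance that includes replicate 3 of mrps-38(P210L), and were 19 higher and 6 lower in a fit of only these 2 groups, and 18 and 6 without that library. All 29 markers of body wall muscle fell (median -0.94), including the myosin heavy chain unc-54 (-1.2 ± 0.07) and troponin I tni-1 (-1.77 ± 0.06). Molting genes fell in 36 of 41 cases and rose in 1 (median -0.81, wrt-4 at -2.14 ± 0.21). Camera called the oocyte, vitellogenin, muscle and molting lists with adjusted p of 5.69e-18, 0.0226, 1.07e-14 and 3.45e-09, and with an estimated correlation their adjusted p was 0.237 to 0.427. Collagens went both ways, 53 of 163 higher and 79 lower, with a median of -0.39, a mean of 1.07 and a camera adjusted p = 0.194 in the downward direction. C09E7.8 had 1115 reads over the wildtype libraries and none in lonp-1(cmh24), at least 145-fold lower against a floor of 3 reads per library.

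In total 9848 genes changed between lonp-1(cmh24) and wildtype, 4805 higher and 5043 lower, of which 1713 rose and 1037 fell at least 2-fold. Camera called 30 of 50 lists, 11 higher and 19 lower, and none with an estimated correlation (adjusted p = 0.0635 to 0.52). Adjusted over the list alone, the counts of the lists named for this comparison were the same apart from 25 lower for the large mitoribosomal subunit, 15 lower for complex V, 25 lower for beta-oxidation, 37 higher for P450 genes, and 55 higher and 80 lower for collagens. Scaling to total reads raised the median of all genes by 0.23, so that 67.1% of the calls on FPKM were higher (51.8% with TMM factors), against 48.8% with the authors' size factors.

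**Figure D2:**
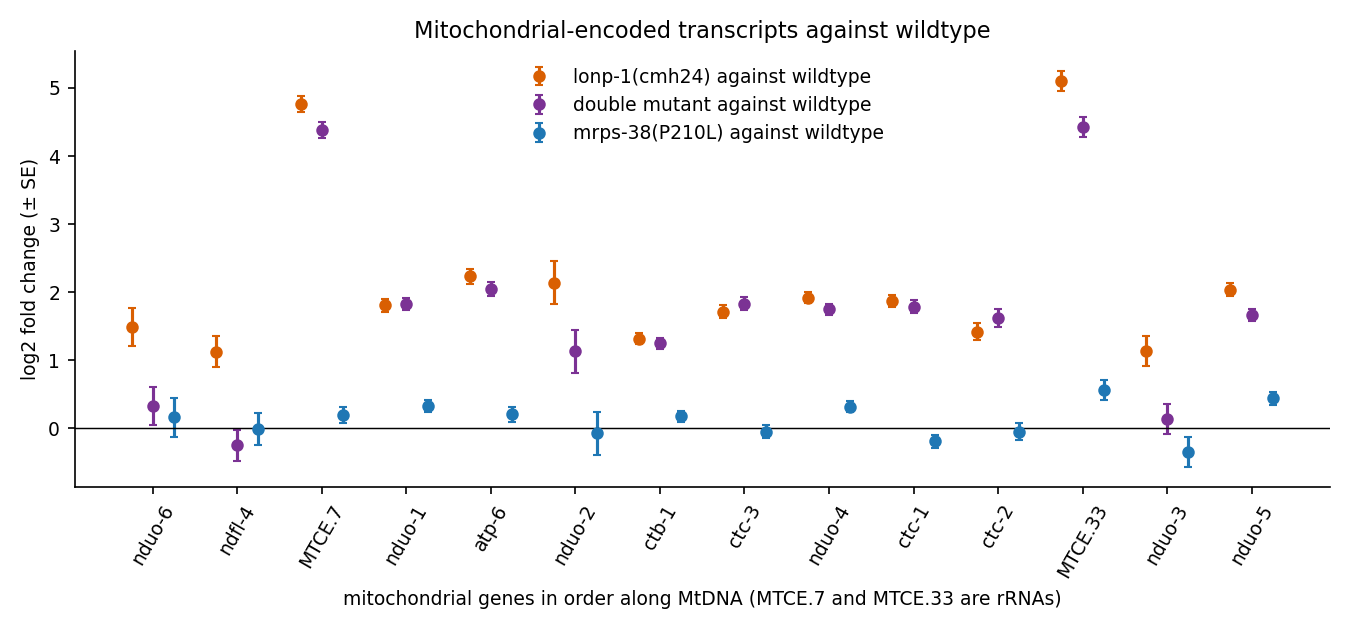
Log2 fold change against wildtype (bars are SE, n = 3 libraries per group) of the 12 mRNAs and 2 rRNAs encoded by mitochondrial DNA, in their order along the molecule, for lonp-1(cmh24), the double mutant and mrps-38(P210L). The rRNAs sit at 4.39 to 5.11 in both groups with the lonp-1 mutation, and the median of the 12 mRNAs in mrps-38(P210L) was 0.08, which became -0.18 under total-read scaling.

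The comparison of mrps-38(P210L) with wildtype asked what the mitoribosomal mutation did alone. Transcripts of yolk, sperm and oocytes were far lower in the mutant, while nuclear genes for respiration, the TCA cycle and cytosolic ribosomes were higher. All 6 vitellogenins fell (median -7.43), with vit-5 at -7.89 ± 0.91 and vit-2 at -7.82 ± 1.03. With 45 reads of vit-5 over the mrps-38(P210L) libraries, the size of its fall depends in part on the pseudocount. All 31 major sperm proteins fell (median -4.28, msp-33 at -5.68 ± 0.48). So did 54 of 56 spermatogenesis genes (median -3.66, 1 higher), among them spe-11 (-5.45 ± 0.74) and ssq-1 (-5.01 ± 0.63). Oocyte and eggshell genes fell in 30 of 37 cases and rose in 3 (median -1.39, perm-4 at -5.13 ± 0.85). Genes of germline proliferation and meiosis fell in 33 of 45 with 4 higher (median -0.74). Camera called these 5 lists with adjusted p of 0.00162 to 3.7e-14, and with an estimated correlation their adjusted p was 0.347 to 0.419. The adult cuticle collagen col-19 fell too (-7.43 ± 1.09), as did the transthyretin-related gene ttr-14 (-8.38 ± 0.96). Heterochronic genes, which time the larval stages, rose in 8 of 12 cases and fell in 2, with lin-41 at 2.75 ± 0.14 and the nuclear receptor daf-12 at 1.87 ± 0.08 (median 0.74, camera adjusted p = 0.00519, and adjusted p = 0.333 with an estimated correlation).

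Of the 12 mitochondrial mRNAs, 3 rose, nduo-5 (0.44 ± 0.09), nduo-1 (0.33 ± 0.09) and nduo-4 (0.32 ± 0.08), but on FPKM and with total-read scaling none rose and 3 fell. The list was not called (camera adjusted p = 0.373), and its median of 0.08 became -0.18 under total-read scaling. The mitochondrial stress response list rose in 18 of 27 cases and fell in 2 (median 0.38, camera adjusted p = 0.000896, and adjusted p = 0.318 with an estimated correlation), and on FPKM in 12 with 6 lower (median 0.10). hsp-6 rose by 0.81 ± 0.08, hsp-60 by 0.57 ± 0.07 and atfs-1 by 1.05 ± 0.04. Nuclear-encoded respiratory complexes rose, with 29 of 33 members of complex I (gas-1 at 0.83 ± 0.06), 9 of 11 of complex III (ucr-2.1 at 1.2 ± 0.09), 16 of 24 of complex IV and 13 of 16 of complex V (asb-2 at 1.04 ± 0.08) higher. The numbers lower were 2, 1, 3 and 1. On FPKM only 13 members of complex I rose and 5 fell (median 0.06), and for complex IV 10 rose and 6 fell (median 0.06), while complexes III and V had 7 and 12 higher. The TCA cycle rose in 22 of 26 cases and fell in 3 (18 and 4 on FPKM), including the pyruvate carboxylase pyc-1 (0.98 ± 0.07) and the citrate synthase cts-1 (0.60 ± 0.08). Medians of these 5 lists were 0.32 to 0.55 and camera adjusted p were 1.84e-06 to 0.00455, and with an estimated correlation their adjusted p was 0.25 to 0.333.

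Cytosolic ribosomal proteins rose in 76 of 84 cases and fell in 2 (median 0.49, rpl-3 at 0.60 ± 0.06, camera adjusted p = 8.91e-14, and adjusted p = 0.371 with an estimated correlation), with rpl-42 as the strongest exception (-3.93 ± 0.64). Mitoribosomal proteins rose in 19 of 42 cases for the large subunit and 16 of 28 for the small one, with 3 and 1 lower, but on FPKM 6 and 0 were higher and 18 and 11 lower, and their medians of 0.16 and 0.20 became -0.09 and -0.05 under total-read scaling (camera adjusted p = 0.00954 and 0.0171, and adjusted p = 0.386 for both with an estimated correlation). HIF-1 and sulfide response genes rose in 10 of 14 cases and none fell (median 0.68), among them the sulfide oxidase sqrd-1 (2.25 ± 0.21) and the prolyl hydroxylase egl-9 (1.45 ± 0.06). Innate immune effectors rose in 31 of 50 and fell in 4 (median 0.48, on FPKM 20 and 8 with a median of 0.20), with dod-21 (3.23 ± 0.18) and clec-60 (2.71 ± 0.28) higher and dod-23 (-4.79 ± 0.54) lower. Neuron markers rose in 33 of 42 and fell in 1 (median 0.53), including eat-4, the vesicular glutamate transporter (1.37 ± 0.16), and the choline transporter cho-1 (1.17 ± 0.10). Camera called these 3 lists (adjusted p = 0.000896, 2.22e-05 and 1.24e-08), and with an estimated correlation their adjusted p was 0.243 to 0.333. R04F11.3 had no reads in mrps-38(P210L), at least 278-fold fewer than in wildtype.

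The test called 10418 genes between mrps-38(P210L) and wildtype, 4957 higher and 5461 lower, with 861 and 2537 of them at least 2-fold. Of 50 lists, 31 were called, 26 higher and 5 lower, and none with an estimated correlation (adjusted p = 0.243 to 0.579). Adjusted over the list alone, the counts of the lists named above for this comparison were the same but for 55 lower spermatogenesis genes, 6 higher germline genes, 18 higher large-subunit mitoribosomal proteins and 77 higher cytosolic ribosomal proteins. Scaling to total reads lowered the median of all genes by 0.25 (a shift of -0.25), and 25.4% of the calls on FPKM were higher, against 47.6% with the authors' size factors.

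The double mutant was compared with lonp-1(cmh24) to ask what the mitoribosomal mutation did to worms that carry the lonp-1 mutation. Molting genes and many collagens fell, while genes of sperm and of body wall muscle rose. With the authors' size factors most genes of the TCA cycle and of respiratory complexes III and V, which had fallen in lonp-1(cmh24), rose too, but on FPKM only 7 of 26, 5 of 11 and 4 of 16 did. Collagens fell in 100 of 163 cases and rose in 22 (median -0.83, camera adjusted p = 2.37e-11, and adjusted p = 0.00122 with an estimated correlation), with col-37 at -6.04 ± 0.68 and col-44 at -5.64 ± 0.64. In a fit of only these 2 groups 107 collagens fell and 38 rose, and 106 and 36 without replicate 3 of mrps-38(P210L). Molting genes fell in 35 of 41 and rose in 2 (median -1.39), among them the apical matrix genes fbn-1 (-3.11 ± 0.11), dpy-6 (-3.0 ± 0.10) and noah-1 (-2.56 ± 0.09). Heterochronic genes fell in 8 of 12 and rose in 1 (median -0.66), including lin-42, the worm period homolog (-1.66 ± 0.09), and the microRNA gene let-7 (-1.25 ± 0.11). All 31 major sperm proteins rose (median 2.39, msp-63 at 3.04 ± 0.41). So did 53 of 56 spermatogenesis genes with 1 lower (median 1.77, ssp-19 at 2.62 ± 0.65). Neuron markers fell in 28 of 42 cases and none rose (median -0.35, snt-1 at -0.79 ± 0.10). Camera called these 5 lists besides the collagens (adjusted p = 3.51e-17 to 0.00266), and with an estimated correlation their adjusted p was 0.233 to 0.599. The vitellogenin list was not called (median 1.52, camera adjusted p = 0.115). Of its members 2 of 6 rose (1 of 6 adjusted over the list alone) with a variance that includes replicate 3 of mrps-38(P210L), and all 6 in a fit of only these 2 groups or without that library. Also not called was the oocyte list (median -0.03, camera adjusted p = 0.855).

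Markers of body wall muscle, all of which had fallen in lonp-1(cmh24), rose in 27 of 29 cases (median 0.58, camera adjusted p = 2.47e-11, and adjusted p = 0.348 with an estimated correlation), with unc-54 at 0.85 ± 0.07, act-4 at 0.73 ± 0.06 and the calponin cpn-3 at 0.95 ± 0.07. TCA cycle genes rose in 21 of 26 and fell in 1 (median 0.25), with cts-1 at 0.54 ± 0.08 and the dihydrolipoamide dehydrogenase dld-1 at 0.54 ± 0.05. Complex III rose in 9 of 11 (median 0.29, ucr-1 at 0.42 ± 0.06) and complex V in 13 of 16 (median 0.28, atp-1 at 0.33 ± 0.05). These rises depended on the scaling. On FPKM the TCA cycle had 7 higher and 3 lower (median 0.03), complex III 5 higher (0.08) and complex V 4 higher and 2 lower (0.07), and with TMM factors 10, 5 and 6 members were higher. Camera called these 3 lists (adjusted p = 0.000113 to 0.00216), and with an estimated correlation their adjusted p was 0.233 to 0.524. For complex I (16 of 33 higher) and cytosolic ribosomal proteins (30 of 84 higher, 1 lower) the medians of 0.14 and 0.13 became -0.07 and -0.08 under total-read scaling, with 1 higher and 9 lower and with 4 higher and 16 lower on FPKM (camera adjusted p = 0.00233 and 0.00156, and adjusted p = 0.524 and 0.739 with an estimated correlation). In a fit of only these 2 groups 40 cytosolic ribosomal proteins were higher and 2 lower. fat-7 rose by 2.88 ± 0.18 and acdh-2 by 2.21 ± 0.20 after their falls in lonp-1(cmh24).

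Among transcripts of the mitochondrial genome, 5 of the 12 mRNAs and both rRNAs fell, and on FPKM and with TMM factors 9 and 8 of the mRNAs did (medians -0.39 and -0.33). The 5 mRNAs were ndfl-4 (-1.38 ± 0.23), nduo-6 (-1.15 ± 0.28), nduo-2 (-1.01 ± 0.32), nduo-3 (-1.0 ± 0.22) and nduo-5 (-0.37 ± 0.09), while the list was not called (median -0.18, camera adjusted p = 0.101). The rRNA genes fell by 0.38 (MTCE.7, SE 0.12) and 0.67 (MTCE.33, SE 0.15) on the log2 scale. The calls of MTCE.7 and of nduo-2 were each lost without any 1 of 3 libraries of these groups. hsp-6 stood at 0.04 ± 0.08 (adjusted p = 0.715), but at -0.18 with total-read scaling, where it passed (adjusted p = 0.0435), and at 0.09 with arrayWeights, where it also passed (0.0347, in a range of 0.0347 to 0.939 over the alternatives). hsp-60 stood at -0.15 ± 0.07 (adjusted p = 0.104), and passed as a fall on FPKM, with total-read scaling, TMM factors and arrayWeights, in edgeR and in a fit of only the groups compared. By contrast atfs-1 rose by 0.24 ± 0.05, a call that was lost with TMM factors, on FPKM, with total-read scaling and in edgeR. fmo-2 fell by 1.16 on the log2 scale (SE 0.21). The intracellular pathogen response fell in 12 of 29 cases and rose in 2 (median -0.50, pals-27 at -2.25 ± 0.38, camera adjusted p = 0.034, and adjusted p = 0.607 with an estimated correlation).

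In this comparison 8538 genes changed, 4687 higher and 3851 lower, with 1860 and 1192 at least 2-fold. The direction of the balance depended on the scaling, since 31.2% of calls were higher on FPKM and 36.3% with TMM factors against 54.9% in the main test, with shifts of the median of all genes of -0.21 and -0.15. Camera called 23 of 50 lists, 15 higher and 8 lower, and only collagens with an estimated correlation. Adjusted over the list alone, counts differed for collagens (23 higher), molting genes (36 lower), spermatogenesis genes (54 higher), complex III (10 higher), complex V (14 higher), cytosolic ribosomal proteins (20 higher) and oocyte genes (3 higher, 1 lower), and were the same for the other lists named here.

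Of the 9848 genes that changed in lonp-1(cmh24), 2853 (29%) changed back in the double mutant, 2471 changed further in the same direction and 4524 were not called between the double mutant and lonp-1(cmh24). The 2853 held 1163 genes that had been higher and 1690 that had been lower, where independent lists of these sizes would share 1177 and 1504, and 20 simulations of unchanged groups that shared the lonp-1 libraries gave none. Without effects almost no gene is called, so that 0 says nothing about a return towards wildtype. The division depended on the scaling, with 3017 and 718 such genes on FPKM and 1987 and 1090 with TMM factors. Among genes that changed back, 1256 no longer differed from wildtype by the test, 1109 still differed on the same side and 488 had passed to the other side. For genes at least 2-fold higher in lonp-1(cmh24), the share of the change that was reversed, measured in held-out libraries, was 9.67 ± 1.5% (SD over 3 held-out replicates). For lower genes it was -20 ± 14.9%, which is a median farther from wildtype in the double mutant than in lonp-1(cmh24). With no fold limit the shares were 1.15% and 7.12%, so the sign of the share of lower genes depended on that limit, and on FPKM they were 17.8% and -37%.

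The double mutant was next set against wildtype, to see which differences were left. The mitochondrial rRNAs were still high, MTCE.7 at 4930 ± 240 and MTCE.33 at 2180 ± 140 normalized counts (SD, n = 3), with log2 fold changes of 4.39 ± 0.12 and 4.43 ± 0.15. Of the mitochondrial mRNAs 9 of 12 rose (median 1.64, camera adjusted p = 0.00115, and adjusted p = 0.418 with an estimated correlation), among them atp-6 (2.05 ± 0.11), ctc-3 (1.83 ± 0.09) and nduo-1 (1.83 ± 0.09). nduo-3 (0.14 ± 0.22), ndfl-4 (-0.25 ± 0.23) and nduo-6 (0.33 ± 0.28) did not pass. The mitochondrial stress response rose in 20 of 27 cases and fell in 5 (median 0.45, camera adjusted p = 0.00579, and adjusted p = 0.418 with an estimated correlation), with hsp-6 at 0.75 ± 0.08, atfs-1 at 0.88 ± 0.04 and fmo-2 at 2.79 ± 0.21. hsp-60 fell (-0.57 ± 0.07). Complex I fell in 21 of 33 and none rose (median -0.17), and mitoribosomal proteins of the large subunit fell in 27 of 42 (median -0.21). Cytosolic ribosomal proteins fell in 78 of 84 with 2 higher (median -0.46, rpl-3 at -0.57 ± 0.06). Camera called these 3 lists (adjusted p = 0.00141, 0.000445 and 4.36e-12), and with an estimated correlation their adjusted p was 0.418. Complexes III, IV and V and the TCA cycle, with medians of -0.08, -0.07, -0.12 and -0.03, were not called (camera adjusted p = 0.312 to 0.594).

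Glycolysis rose in 14 of 19 cases and fell in 1 (median 0.45), with hxk-1 at 1.56 ± 0.05 and gpd-1 at 1.58 ± 0.14. Genes of the propionate shunt and methionine cycle fell in 19 of 27 and rose in 3 (median -0.62, ahcy-1 at -1.13 ± 0.12). Genes of endoplasmic reticulum stress fell in 14 of 22 and rose in 3 (median -0.48), with the protein disulfide isomerase pdi-2 at -1.34 ± 0.08 and dnj-27 at -1.93 ± 0.09. These 3 lists were called (camera adjusted p = 0.00826, 0.00037 and 0.00194), and with an estimated correlation their adjusted p was 0.418 to 0.445. The intracellular pathogen response rose in 19 of 29 and fell in 3 (median 1.11, skpo-1 at 3.58 ± 0.24, camera adjusted p = 0.0185, and adjusted p = 0.487 with an estimated correlation). All 6 vitellogenins (median 4.54, vit-5 at 5.07 ± 0.91), all 37 oocyte genes (median 2.56, meg-1 at 5.69 ± 0.48), 29 of 31 major sperm proteins (median 2.71, msp-63 at 3.68 ± 0.41) and 42 of 45 germline genes (median 0.75) rose and none fell. Molting genes fell in 38 of 41 with 1 higher (median -2.34, wrt-10 at -4.04 ± 0.06), and neuron markers in 35 of 42 (median -0.63, the tubulin mec-7 at -1.39 ± 0.06). Camera called these 6 lists (adjusted p = 5.02e-16 to 0.0185), and with an estimated correlation their adjusted p was 0.258 to 0.576. Body wall muscle fell in 26 of 29 with 1 higher, by less than in lonp-1(cmh24) at the median (-0.34, unc-54 at -0.34 ± 0.07, camera adjusted p = 2.97e-06, and adjusted p = 0.418 with an estimated correlation).

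Between the double mutant and wildtype 11704 genes changed, 6422 higher and 5282 lower, with 2877 and 1890 at least 2-fold. The median of all genes moved by -0.11 with TMM factors, where 47.9% of calls were higher, against 54.9% with the authors' size factors. Camera called 27 lists, 11 higher and 16 lower, and only collagens (median -0.90, mean -0.12, 51 higher and 87 lower of 163, adjusted p = 0.0468) with an estimated correlation. Adjusted over the list alone, the counts of the lists named for this comparison were the same except for 5 lower members of complex IV instead of 7.

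The effect of the lonp-1 mutation in mrps-38(P210L) worms, the double mutant against mrps-38(P210L), covered the widest range of maturation markers. Mitochondrial mRNAs rose in 9 of 12 cases (median 1.33, ctc-1 at 1.98 ± 0.09 and atp-6 at 1.84 ± 0.11, camera adjusted p = 0.00586, and adjusted p = 0.389 with an estimated correlation), and the rRNAs by 4.19 ± 0.12 (MTCE.7) and 3.87 ± 0.15 (MTCE.33). hsp-6 did not change by the test (-0.06 ± 0.08, adjusted p = 0.486, but 0.21 with adjusted p = 0.0181 on FPKM, in a range of 0.0138 to 0.744 over the alternatives), hsp-60 fell (-1.14 ± 0.07), and atfs-1 stood at -0.17 ± 0.04 but at 0.1 on FPKM. TCA cycle genes fell in 22 of 26 cases (median -0.48, suca-1 at -0.94 ± 0.06; on FPKM 16 fell and 6 rose, median -0.21), and complex V in 14 of 16 with 1 higher (median -0.72, atp-2 at -0.78 ± 0.07). Cytosolic ribosomal proteins fell in 80 of 84 with 2 higher (median -0.94, rpl-3 at -1.17 ± 0.06). HIF-1 and sulfide response genes fell in 11 of 14 with 2 higher (median -0.76), with cysl-2 at -2.92 ± 0.09 and sqrd-1 at -2.19 ± 0.21. Camera called these 4 lists (adjusted p = 1.53e-14 to 0.00447), and with an estimated correlation their adjusted p was 0.324.

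All 6 vitellogenins rose (median 11.58, vit-5 at 12.95 ± 0.91 and vit-2 at 12.45 ± 1.03), with all 31 major sperm proteins (median 7.13, msp-65 at 7.93 ± 0.70). The value of vit-5 rests on 45 reads over the mrps-38(P210L) libraries and depends in part on the pseudocount. Of the oocyte genes 34 of 37 rose and 1 fell (median 3.84, perm-2 at 10.06 ± 0.93 and meg-1 at 8.59 ± 0.48). Molting genes fell in 37 of 41 with 1 higher (median -2.50, fbn-1 at -4.26 ± 0.11 and noah-2 at -4.19 ± 0.10). Heterochronic genes fell in 10 of 12 with 2 higher (median -1.27, lin-42 at -2.92 ± 0.09) and neuron markers in 39 of 42 (median -1.27, eat-4 at -2.05 ± 0.16 and cho-1 at -1.92 ± 0.10). Camera called these 6 lists (adjusted p = 1.3e-10 to 0.00395), and with an estimated correlation their adjusted p was 0.276 to 0.404. The adult collagen col-19 rose by 11.23 ± 1.09 and the peroxidase gene skpo-1 by 6.37 ± 0.24, while tba-8, a tubulin, fell by 7.92 on the log2 scale (SE 0.28). R04F11.3 was at least 456-fold higher than in mrps-38(P210L), where it had no reads. In all, 13141 genes changed, 6857 higher and 6284 lower, with 4104 and 2923 at least 2-fold. Camera called 30 lists, 7 higher and 23 lower, none with an estimated correlation (adjusted p = 0.0904 to 0.447), and the counts of the lists named here were the same adjusted over the list alone. Scaling to total reads raised the median of all genes by 0.27, and 62.8% of calls on FPKM were higher (48.8% with TMM factors), against 52.2% with the authors' size factors.

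**Figure D3:**
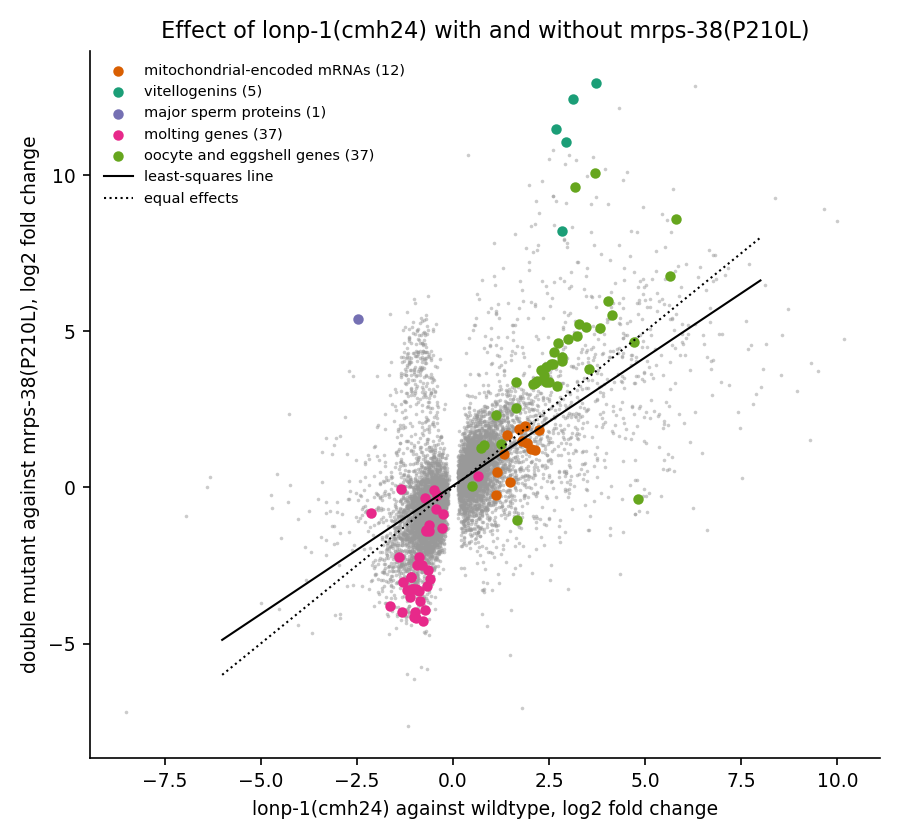
Each point is 1 of the 9848 genes that changed in lonp-1(cmh24), with the log2 fold change of lonp-1(cmh24) against wildtype on the x axis and of the double mutant against mrps-38(P210L) on the y axis; coloured points mark mitochondrial mRNAs, vitellogenins, major sperm proteins, molting genes and oocyte genes. The least-squares line has a slope of 0.822, and the line of equal effects is drawn beside it.

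Across the 9848 genes that changed in lonp-1(cmh24), the effect of the lonp-1 mutation in mrps-38(P210L) followed that in the wildtype background with a slope of 0.822 (Pearson r = 0.623, Spearman rho = 0.639, across genes, which are not independent replicates). Of these genes 81.5% had the same sign. Outside the lists of maturation, germline, collagen and molting genes the slope was 0.815 (r = 0.624, 9584 genes). Those lists hold so few of the 9848 genes that this slope could hardly differ, and it does not separate the effect from maturation. Over all 15717 tested genes the slope was 0.73 (r = 0.384), with 70.9% of the same sign. The interaction of the 2 mutations, which tests whether the effect of one differs with the other, passed for 10377 genes, 5413 higher and 4964 lower, but with TMM factors 4704 were higher and 5952 lower, and in edgeR 4662 and 5897. It was negative for hsp-6 (-0.77 ± 0.11), hsp-60 (-0.73 ± 0.11) and atfs-1 (-0.81 ± 0.06), so that their levels in the double mutant lay below the sum of the 2 single changes. Vitellogenins (median 8.99) and major sperm proteins (median 6.75) had positive interactions in 6 of 6 and 31 of 31 cases, and molting genes negative ones in 34 of 41 with 3 positive (median -1.68). Camera called these 3 lists (adjusted p = 0.00362, 4.92e-10 and 4.92e-10), and with an estimated correlation their adjusted p was 0.414 to 0.658.

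**Figure D4:**
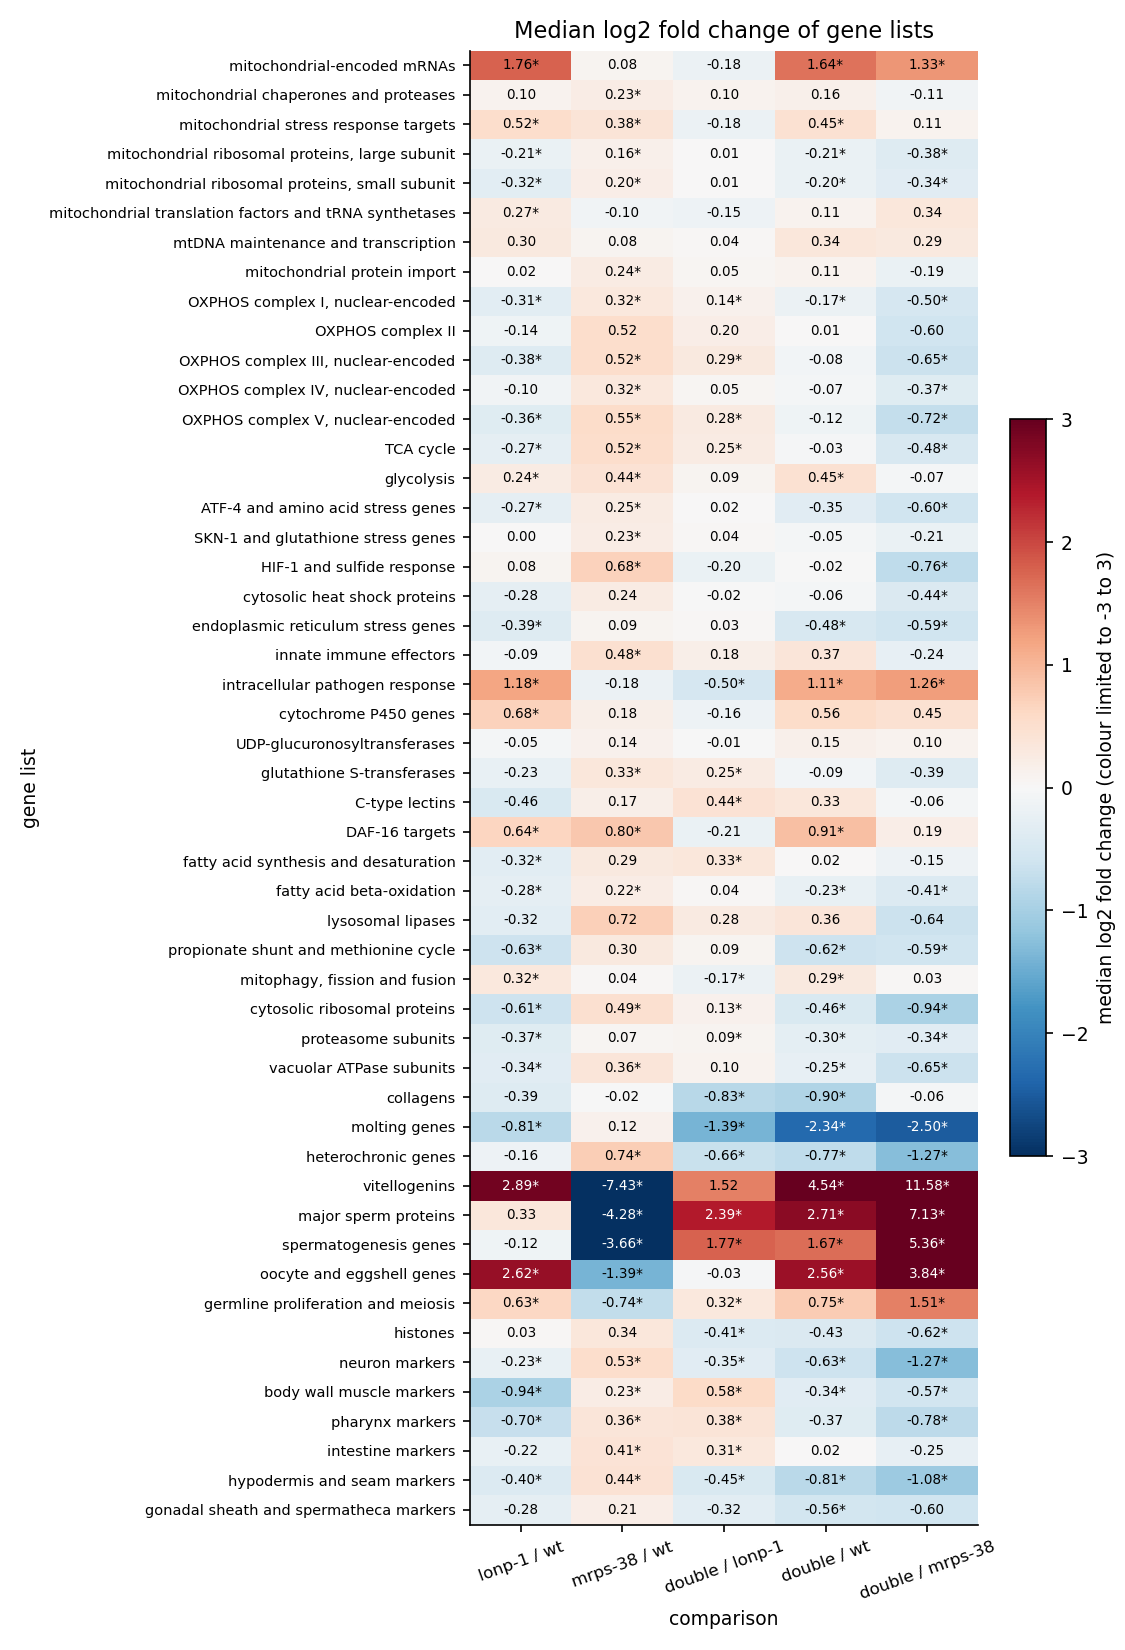
Median log2 fold change of 50 gene lists (vertical axis) in 5 comparisons (horizontal axis), with colour limited to -3 to 3 and an asterisk where the camera adjusted p was under 0.05. Under FPKM scaling the medians of large-subunit mitoribosomal proteins (-0.21 to 0.02 in lonp-1(cmh24), 0.16 to -0.09 in mrps-38(P210L)), and in the double mutant against lonp-1(cmh24) those of complex I (0.14 to -0.07), cytosolic ribosomal proteins (0.13 to -0.08) and proteasome subunits (0.09 to -0.12), changed sign, as did those of other lists named in the text.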

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

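The tests of rRNA carried over, of a rise with age at every step and of replicate 3 of mrps-38(P210L) were chosen only after the results were seen. What singled out the results of this part is that the effect of the lonp-1 mutation differed between the wildtype and the mrps-38(P210L) background, by the interaction in limma. It passed for 10377 genes. The groups also differ in maturation markers, and such markers had the largest medians among the called lists (vitellogenins 8.99, major sperm proteins 6.75). Developmental age and genotype are confounded here, so this interaction does not show by itself that the action of the lonp-1 mutation depends on the background. In 100 random splits of the 12 libraries the highest other count was 6672, with 1 split (the real one) as high. Such splits mix genotypes, which widens the spread within groups and lets effects of single mutations enter the interaction. They argue only against groups without any structure, and cannot decide whether chance played a part in this count. The same splits gave up to 36 called lists against the real 17, with 69 splits as high. For the same reason they cannot decide about chance for the number of lists, where it is not excluded.

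The largest positive interactions were those of vit-2 (9.34), vit-5 (9.22), vit-3 (9.17), col-81 (8.82) and col-181 (8.80), in log2 units. In mrps-38(P210L) vit-5 had 45 reads and vit-3 had 83 over the 3 libraries. The 6 vitellogenins summed to 165.7 and 181.6 normalized counts in replicates 1 and 2 and to 1006 in replicate 3. The size of these vitellogenin values thus depends in part on the pseudocount and on that replicate. R04F11.3 had a fitted value of 10.24, which depends on the pseudocount since mrps-38(P210L) had no reads of it. The largest negative ones were tba-8 (-8.01), col-158 (-7.96), col-36 (-7.20) and nas-3 (-6.85), and the fitted values of F58E6.4 (-8.88) and col-85 (-7.77) rest on 2 reads in the double mutant and 1 read in wildtype. Among genes of the mitochondrial stress response, hsp-6 (-0.77), hsp-60 (-0.73) and atfs-1 (-0.81) had negative interactions, as did the mitochondrial mRNAs nduo-6 (-1.31), ndfl-4 (-1.37), nduo-5 (-0.81), nduo-4 (-0.49) and atp-6 (-0.39), the last with a call that was lost on FPKM and without any 1 of 9 of the 12 libraries. The lonp-1 transcript had a value of 0.17 that did not pass under several alternatives.

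By lists, the interaction was positive for vitellogenins (median 8.99), major sperm proteins (6.75), spermatogenesis genes (5.62), oocyte genes (1.25), germline genes (1.07) and body wall muscle (0.42). It was negative for molting genes (-1.68), heterochronic genes (-1.38), HIF-1 and sulfide response (-1.19), hypodermis and seam markers (-1.02), neuron markers (-0.89), DAF-16 targets (-0.86), histones (-0.80), collagens (-0.56), mitochondrial stress response targets (-0.43), cytosolic ribosomal proteins (-0.35) and the TCA cycle (-0.25). Camera called these 17 lists, and none was called with an estimated correlation (adjusted p = 0.165 to 0.658).

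Mitochondrial transcripts were higher in both groups with the lonp-1 mutation. The authors' size factors are argued against as the cause, since the median of the 12 mRNAs was 1.99 on FPKM. Nuclear and mitochondrial ribosomal RNA carried over together in library preparation is argued against too. The 2 nuclear rRNA genes in the table had a median log2 fold change of -0.61 while the mitochondrial rRNAs rose. This rests on 2 genes, and a carry-over of mitochondrial rRNA alone was not tested. A rise with age at every step would not alone give the median of 0.08 between mrps-38(P210L) and wildtype, where the vitellogenins differed by a median of -7.43. Nor would it alone give that of -0.18 between the double mutant and lonp-1(cmh24). Both comparisons also differ by the mrps-38 mutation, and an effect of that mutation could offset one of age. Such a rise is therefore not excluded. A rise that sets in only between the ages of the wildtype and lonp-1(cmh24) samples was not tested and stays open beside the genotype, since age and genotype are confounded in these groups.

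Replicate 3 of mrps-38(P210L) stood apart from replicates 1 and 2 in the maturation markers. Wildtype worms mixed into the sample would have to make up 3.65% of its RNA by vitellogenins, 5.87% by adult collagens, 11.4% by spermatogenesis genes and 14.8% by major sperm proteins, and this 4.05-fold disparity argues against such a mixture as the sole cause. A later developmental age of that sample may account for it, as its difference from the other replicates correlated across genes with the double mutant minus lonp-1(cmh24) (r = 0.49) and with the double mutant minus wildtype (r = 0.31), which share no library with it, but not with lonp-1(cmh24) minus wildtype (r = -0.03). No further explanation was tested, since the replicates of a group share their genotype.

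Oocyte transcripts were higher in both groups with the lonp-1 mutation. Embryos in these samples could bring such transcripts, and the test was the median of 6 genes first transcribed in the embryo, which was -0.15 in lonp-1(cmh24) against wildtype (2 rose, 3 fell, from -1.12 to 0.42). That bound, set beforehand as an exclusion, was not a fair one, because lin-26 and sdz-24 were already at 1212 and 1831 normalized counts in wildtype and would hide a small share of embryos, and because the 15 further zygotic genes lay below the filter and were not tested singly. Their sum was 27.6 ± 6.7 normalized counts in wildtype, 81.7 ± 22 in lonp-1(cmh24) and 48.4 ± 2.7 in the double mutant (SD, n = 3), with some members lower in lonp-1(cmh24) than in wildtype. Age is left undecided as well, since the oocyte list in replicate 3 of mrps-38(P210L) lay 0.37 above replicates 1 and 2 at the median, between the bounds set for it, with 35 of 37 genes above 0. In the double mutant against lonp-1(cmh24) its median was -0.03, where those of vitellogenins and major sperm proteins were 1.52 and 2.39. That comparison also differs by the mrps-38 mutation, so it does not decide about age. Embryos, age and genotype therefore cannot be told apart for the oocyte transcripts, because neither test was decisive and the markers with low counts are few.

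For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. Every split but the real one also puts both genotypes in both groups, which widens the spread within groups. Counts of genes and lists in those splits therefore cannot decide about chance, and 0 genes in them is no support. Only 1 of the 10 splits, the real one, gave as many genes in each comparison, with 9848, 10418, 8538, 11704 and 13141 genes for lonp-1(cmh24) and mrps-38(P210L) against wildtype and the double mutant against lonp-1(cmh24), wildtype and mrps-38(P210L), and 0 as the highest other count in each. In the same order, the real splits gave 30, 31, 23, 27 and 30 lists, the highest others 27, 30, 27, 25 and 30, and 1, 1, 4, 1 and 2 splits gave as many. For the 2853 genes changed back, 5 of 100 splits of the 9 libraries gave as many and the highest other gave 6744. These splits mix genotypes as well, so they cannot decide about chance, which is not excluded for that count. A split with more than the real count points to a structure of the samples.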

How the results depend on the processing

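Scaling to total reads and TMM factors for the lists were alternatives chosen after seeing the data. Over all alternatives, 355 values of genes other than lonp-1 gave 9099 results with the same direction and side of the threshold, 63 that no longer passed, 26 that newly passed and 5 that reversed (19 had no DESeq2 adjusted p). List calls gave 2900 kept, 257 lost and 3 reversed results. Counts by direction moved by over 1.5 times in mrps-38(P210L) against wildtype (2617 higher on FPKM, from 4957), in lonp-1(cmh24) against wildtype (3218 lower on FPKM, from 5043) and in the double mutant against lonp-1(cmh24) (2992 higher and 6592 lower on FPKM, 5954 lower in edgeR, from 4687 and 3851), and about as far with total-read scaling. Total gene counts stayed within 1.5 times their value apart from genes changed back and changed further, 5298 and 4120 with arrayWeights (whose convergence tolerance was not reached) against 2853 and 2471. Replicate numbers did not pair the libraries (mean r = -0.001), and a replicate block gave 2809. Leaving out single libraries gave 2290 to 3345 genes changed back and 9040 to 10511 genes in lonp-1(cmh24) against wildtype. For the changes named here the cause was not tested, and depth limits only genes with few reads.

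For the lonp-1 transcript, lonp-1(cmh24) against wildtype was -0.1 on FPKM and with total-read scaling (adjusted p = 0.113 and 0.0991). mrps-38(P210L) against wildtype was -0.32 with both and passed (0.000254 and 0.000106, to 0.71 over all alternatives). The double mutant against lonp-1(cmh24) was 0.1 with arrayWeights and passed (0.00995, to 0.381). The double mutant against mrps-38(P210L) was -0.17 in the main test (adjusted p = 0.0048). It reversed to 0.1 on FPKM and with total-read scaling (0.0923 and 0.0795, with 0.000116 as the lowest over all alternatives). Its interaction lost its call with no filter (0.17), TMM factors (0.04), edgeR (0.04), DESeq2 (0.15) and the replicate block (0.17), and 8 of 12 fits without 1 library lost it. Those 12 fits ranged from 0.14 (without wildtype replicate 2, call lost) to 0.19 (without wildtype replicate 3, call kept), and all alternatives had adjusted p of 0.0238 to 0.626.

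With total-read scaling hsp-6 was -0.18 in the double mutant against lonp-1(cmh24) and passed. In the double mutant against mrps-38(P210L), hsp-6 reversed to 0.21 and atfs-1 to 0.1, both on FPKM and with total-read scaling. The proteasome list of the double mutant against lonp-1(cmh24) reversed to a lower direction without a call (adjusted p = 0.205 on FPKM, 0.252 with total-read scaling and 0.883 with TMM factors). With an estimated correlation 0 lists were called for lonp-1(cmh24) and for mrps-38(P210L) against wildtype, 1 each for the double mutant against lonp-1(cmh24) and against wildtype, and 0 for the double mutant against mrps-38(P210L) and for the interaction. fry called 37, 42, 46 and 36 for the last 4 in that order.

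The share reversed was 1.15% for higher genes and 7.12% for lower ones with no fold limit, 13.2% for higher genes as a mean over genes, and 17.8% and -37% on FPKM. The slope was 0.759 for genes changed at least 2-fold, 0.73 over all tested genes, and 0.749 without mrps-38(P210L) replicate 3 to 0.856 without wildtype replicate 2.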

Other observations

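Lists not described in the comparisons moved as well. In lonp-1(cmh24) against wildtype, DAF-16 targets rose in 12 of 20 cases and none fell (median 0.64), among them sip-1 (4.33 ± 0.13, log2 fold change ± SE, n = 3), dod-3 (4.11 ± 0.19) and the ferritin ftn-1 (2.89 ± 0.28). Genes of endoplasmic reticulum stress fell in 14 of 22 and rose in 4 (median -0.39), with the calreticulin crt-1 at -1.0 ± 0.06 and pdi-3 at -0.94 ± 0.05. ATF-4 and amino acid stress genes fell in 15 of 24 and rose in 3 (median -0.27), with the asparagine synthetase asns-1 at -1.02 ± 0.07. Pharynx markers fell in 16 of 22 and rose in 2 (median -0.70, myo-2 at -1.4 ± 0.09), and vacuolar ATPase subunits fell in 16 of 20 and rose in 2 (median -0.34). Neuron markers fell in 20 of 42 and rose in 2 (median -0.23), and germline genes rose in 31 of 45 and fell in 4 (median 0.63). Hypodermis and seam markers fell in 12 of 22 and rose in 5 (median -0.40), and genes of fatty acid synthesis fell in 13 of 25 and rose in 4 (median -0.32). On FPKM the counts were closer to even, with 10 lower and 7 higher for ATF-4 genes, 7 and 3 for vacuolar ATPase, 11 and 10 for neuron markers, 8 and 5 for hypodermis and 8 and 9 for fatty acid synthesis (medians -0.17 to 0.00). Camera called these 9 lists (adjusted p = 2.18e-06 to 0.0427), and with an estimated correlation their adjusted p was 0.237 to 0.52. Not called were chaperones and proteases (median 0.10), mitochondrial DNA maintenance (0.30), protein import (0.02), complexes II (-0.14) and IV (-0.10), HIF-1 and sulfide response (0.08), heat shock proteins (-0.28, hsp-16.41 at -2.05 ± 0.10), C-type lectins (-0.46), lysosomal lipases (-0.32), histones (0.03), heterochronic genes (-0.16), spermatogenesis genes (-0.12), intestine (-0.22) and gonadal sheath markers (-0.28), and the immune (-0.09), SKN-1 (0.00), glucuronosyltransferase (-0.05) and glutathione S-transferase (-0.23) lists. Scaling to FPKM changed the sign of complexes II and IV and of the immune, both transferase, heterochronic, spermatogenesis and intestine medians.

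In mrps-38(P210L), glycolysis rose in 14 of 19 cases and fell in 3 (median 0.44), DAF-16 targets in 13 of 20 with 2 lower (median 0.80, sod-3 at 1.74 ± 0.18 and icl-1 at 1.86 ± 0.10), glutathione S-transferases in 18 of 38 with 3 lower (median 0.33), vacuolar ATPase subunits in 18 of 20 with 2 lower (median 0.36), and pharynx, intestine and hypodermis markers in 14 of 22, 20 of 34 and 15 of 22 with 1, 3 and 2 lower (medians 0.36, 0.41 and 0.44). On FPKM far fewer passed, 5 higher and 2 lower for vacuolar ATPase (median 0.10), 7 and 6 for intestine (0.16), 7 and 2 for pharynx (0.10), 10 and 4 for hypodermis (0.18), 9 and 5 for glutathione S-transferases (0.14) and 8 and 3 for DAF-16 targets (0.52). Camera called these 7 lists (adjusted p = 0.000952 to 0.0104), and with an estimated correlation their adjusted p was 0.243 to 0.579. Chaperones, import, ATF-4, SKN-1, beta-oxidation and muscle lists were called higher (adjusted p = 0.0029 to 0.0428, and adjusted p = 0.243 to 0.566 with an estimated correlation) with medians of 0.22 to 0.25 that fell to between -0.03 and -0.01 on FPKM. In the double mutant against lonp-1(cmh24), C-type lectins rose in 66 of 129 with 23 lower (median 0.44), fatty acid synthesis in 16 of 25 with 3 lower (median 0.33) and germline genes in 23 of 45 (median 0.32, gld-1 at 0.66 ± 0.09). On FPKM the germline genes divided into 10 higher and 9 lower (median 0.11), and fatty acid synthesis into 11 and 7 (median 0.11). Histones fell in 18 of 36 with 7 higher (median -0.41), hypodermis and seam markers in 13 of 22 with 3 higher (median -0.45, dpy-7 at -2.58 ± 0.05) and mitophagy genes in 12 of 26 with 3 higher (21 and 1 on FPKM and with TMM factors, medians -0.17, -0.38 and -0.32, dct-1 at -0.80 ± 0.09). These 6 lists were called (camera adjusted p = 0.000931 to 0.0395), and with an estimated correlation their adjusted p was 0.19 to 0.661. twnk-1, the mitochondrial DNA helicase, fell by 0.92 on the log2 scale (SE 0.13) in that comparison and by 1.58 (SE 0.13) in the double mutant against wildtype. Adjusted over the list alone, counts of this section differed for lonp-1(cmh24) in endoplasmic reticulum stress (15 lower) and neuron markers (19 lower), for mrps-38(P210L) in intestine markers (22 higher), and for the double mutant against lonp-1(cmh24) in C-type lectins (67 higher), histones (19 lower) and hypodermis markers (15 lower).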
